A study of Mus musculus with 24 samples.

How the data were processed

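Bulk RNA-seq of mouse proximal jejunum was deposited as gene counts for 24 libraries. The tissue had been separated into an epithelial fraction and the remaining tissue without epithelium, called lamina propria here. The values are whole-number read counts per gene, which the authors deposited without normalisation, in 1 table for each fraction. Each table holds the same 22740 genes, all of the protein-coding biotype, so ribosomal and other noncoding RNA cannot be assessed. Per the labels, the epithelial libraries were made with a stranded mRNA kit and counted on the reverse strand, and the lamina propria libraries were made with a kit that removes ribosomal RNA and were counted without regard to strand. The molecule label reads poly(A) RNA for every library. The kit and the counting therefore go with the fraction, and levels were compared between fractions only to describe which tissue a library holds and, in weighing carry-over, to choose genes higher in lamina propria and to scale rises in the epithelial fraction. In the lamina propria, reads from a gene and from an overlapping or antisense gene cannot be told apart. The label of epithelial dblGATA1 replicate 5 names the other kit and the other table, while its column stands in the reverse-strand table, and it was used there. The sample names of the lamina propria columns contain the abbreviation for epithelial cells, while their titles and cell type labels name the tissue without epithelium. Aligner, counting program, genome build and annotation are not given in the sources used here. Sequencing batches are not given either, and no library was pooled.

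Groups were taken from the titles and genotype labels: 5 libraries each for BALB/c and dblGATA1 in both fractions, and 4 lamina propria libraries of ST2/IL17RB null mice. The series design speaks of replicate mice. No label ties the 2 fractions to the same animals. Total counts per library ran from 24295042 to 30585354 in the epithelial fraction and from 9231953 to 13622891 in the lamina propria. A level of 3 counts over all libraries of a group, the upper limit that a count of 0 allows, is 0.0213 to 0.0218 CPM (counts scaled to library size) in the epithelial groups and 0.051 to 0.061 CPM in the lamina propria groups. Counting intervals and this floor cover counting error only, since the reads carry no molecular identifiers. No 2 libraries of a group agreed within sampling noise, so each was counted as 1 replicate.

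Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total 15) and TMM normalisation, within each fraction. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The lamina propria comparisons used all 14 libraries of that fraction, which share 1 estimate of the spread. The difference between fractions in the dblGATA1 effect was tested as an interaction over 20 libraries. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are on TMM-scaled library sizes and are given as mean ± SD. Log2 CPM for replicate correlations and list levels used a prior count of 2. Gene lists (43, of cell types, pathways and RNA quality) were fixed before the data were examined. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on voom values, with Benjamini-Hochberg adjustment over the lists of a comparison. Each camera adjusted p is given beside the adjusted p with the correlation estimated from the data. Each list's members were also counted with the edgeR p-values adjusted over the list alone.

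Gene positions and transcript GC content came from GENCODE M21 on GRCm38, matched by gene identifier. A position was found for 21842 of the 22740 genes, all on the chromosome that the deposited tables give. GC content was found for 97.6% of the genes tested in the lamina propria. The build of the deposited counts is not given in the sources used here, so positions are those of GRCm38 and were used to place genes, not reads. Enrichment of changed genes within 10 Mb of a targeted gene was tested by a two-sided Fisher's exact test against all other tested genes. Some symbols in the tables are older names: Igj is Jchain, Siglec5 is Siglecf.

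The rule for naming genes was also fixed before the data were examined. It takes the targeted genes, the eosinophil list, up to 8 rises and 8 falls with the largest fold changes among called genes of at least 1 CPM with no overlap between groups, and up to 4 members of each list by p. Antigen receptor segments and genes with only a clone, accession or Gm name were left out of the largest changes. The rule names 669 combinations of gene, reason and comparison. The genes described were picked from these after their values were seen, and the genes of chromosome 1 and the lamina propria values of genes called in the epithelial fraction were also named after their values were seen.

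The tests were run on simulated counts with 200 genes changed by known folds. In the epithelial comparison (11935 genes run) 79.1% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 6.15% of calls were false. For dblGATA1 in the lamina propria (15308 genes) these shares were 14.9%, 64.2% and 90.9%, with 4.24% false. For ST2/IL17RB null against BALB/c (15316 genes) they were 19.4%, 55.2% and 89.4%, with 5.22% false. Between the mutants (15321 genes) they were 11.9%, 55.2% and 87.9%, with 5.5% false, and for the interaction (15619 genes) 19.4%, 49.3% and 71.2%, with 6.06% false. Changes below 2-fold in the lamina propria were therefore often missed at this depth and spread. Genes were simulated independently of each other, without the differences in tissue makeup that move many genes together in the real libraries. The shares of false calls therefore need not hold for the real data.

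Before the data were examined, 56 alternatives were listed. They cover RLE size factors, DESeq2 1.42.0, no filter or a stricter filter on low counts, leaving out antigen receptor segments, the replicate number as a block, other list tests, other windows, and leaving out each library in turn. A further 15 were chosen after seeing the data: removal of each library's trend on GC content (loess, span 0.5), leaving out 5 lamina propria libraries, B cell and absorptive enterocyte levels as covariates, and leaving out the targeted gene in the locus test. The 5 libraries were those whose mean B cell or absorptive enterocyte level lay more than 4-fold above the mean of the fraction. This limit was set after the list levels were seen and before its effect on any count was known.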

Results

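The libraries describe the proximal jejunum of mice kept specific-pathogen-free, as an epithelial fraction and as lamina propria, the tissue left without its epithelium. BALB/c mice were set against dblGATA1 mice, which carry a deletion of a GATA site in the Gata1 promoter and lack eosinophils, to ask what changes in the gut without these cells. ST2/IL17RB null mice lack the receptors for the alarmins IL-33 (ST2, encoded by Il1rl1) and IL-25 (Il17rb), which drive type 2 immunity, and were profiled in the lamina propria. Their background strain is not given in the sources used here. Each group had 5 libraries, except for 4 of ST2/IL17RB null mice. Total counts in the epithelial fraction were 24295042 to 30585354 in BALB/c and 24500679 to 29582764 in dblGATA1, and in the lamina propria 9231953 to 11387582 in BALB/c, 10418223 to 12417081 in dblGATA1 and 11169986 to 13622891 in ST2/IL17RB null. Genes detected per library numbered 14516 to 15097 in the epithelial fraction and 17222 to 17428 in the lamina propria.

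Levels of the marker genes Fabp1 and Col3a1 went with the labels of the fractions. Fabp1, a fatty acid carrier of enterocytes, lay at 3854 to 5888 CPM in the epithelial libraries and at 18.6 to 396 CPM in the lamina propria, and Col3a1, a fibrillar collagen, at 0.489 to 3.00 CPM and 1709 to 3687 CPM. Replicates were more alike in the epithelial fraction, where correlations of log2 CPM across genes between libraries of a group were 0.989 to 0.996, than in the lamina propria, where they were 0.916 to 0.990. Genes are not independent replicates, so these describe likeness only. In the lamina propria, all 10 epithelial carry-over, 15 smooth muscle and 14 enteric neuron genes passed the filter on low counts. This fraction thus also held epithelial, muscle and nerve transcripts. The lamina propria libraries differed in lymphoid and epithelial content. The mean log2 level of B cell genes stood 3.56 above the mean of the fraction in BALB/c replicate 4, 2.86 in dblGATA1 replicate 3 and 2.34 in ST2/IL17RB null replicate 1. That of absorptive enterocyte genes stood 2.47 above it in BALB/c replicate 3 and 2.49 in dblGATA1 replicate 4. Neither list passed the camera test for dblGATA1 against BALB/c in the lamina propria (B cell, median log2 fold change -0.63, camera adjusted p = 0.611; absorptive enterocyte, camera adjusted p = 0.86, where the test points up and the median is marginally below 0; adjusted p = 0.98 with an estimated correlation).

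The targeted genes followed the genotype labels in the lamina propria. Gata1, the transcription factor of erythroid, mast and eosinophil lineages (chromosome X, 7959260 to 7978071), had 55 counts over the 5 BALB/c libraries, 11 over the dblGATA1 libraries and 59 over the ST2/IL17RB null libraries. Its level fell from 1.03 ± 0.494 to 0.191 ± 0.198 CPM in dblGATA1 (log2 fold change -2.38, SE 0.57, edgeR adjusted p = 0.0299), a call that held in 4 of 10 fits that each left out 1 library (highest adjusted p 0.0784, without dblGATA1 replicate 1), with a log2 fold change of -3.11 without dblGATA1 replicate 2. In the epithelial fraction no library had more than 1 Gata1 count, so the label could not be checked there. Il1rl1 (chromosome 1, 40429570 to 40465415) fell from 27.3 ± 16.3 CPM in BALB/c to 5.97 ± 3.15 CPM in ST2/IL17RB null (log2 fold change -2.19, SE 0.43, edgeR adjusted p = 0.0108). Il17rb (chromosome 14, 29996135 to 30008896) fell from 20.7 ± 3.37 to 12.4 ± 1.81 CPM (log2 fold change -0.74, SE 0.14, edgeR adjusted p = 0.00964). The deleted parts of both receptor genes are not given in the sources used here, and counts over the whole gene include any reads outside them.

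In the epithelial fraction of dblGATA1 mice, genes of macrophages and other leukocytes were higher than in BALB/c. C1qa, a complement component made by macrophages (chromosome 4, 136895917 to 136898803), rose 4.61-fold from 0.339 ± 0.0777 to 1.58 ± 0.505 CPM (n = 5 each; edgeR adjusted p = 0.0149). Adamdec1 rose 3.97-fold from 0.577 to 2.32 CPM, and Apoe, a lipid carrier abundant in macrophages, rose 2.98-fold from 2.28 ± 0.258 to 6.78 ± 2.26 CPM (edgeR adjusted p = 0.0281 and 0.0191). Asb2 (2.84-fold), Tspan9 (2.01-fold) and Coro1a, an actin regulator of leukocytes (1.73-fold), also rose, with edgeR adjusted p from 0.00865 to 0.0281. Gstk1, a glutathione transferase of mitochondria and peroxisomes, was the sole gene that fell, from 102 ± 3.48 to 83.9 ± 4.25 CPM (edgeR adjusted p = 0.0411). Of 10 fits that each left out 1 library, Asb2 passed in 9, C1qa in 6, Apoe in 5, Coro1a in 3, Adamdec1 in 2 and Tspan9 and Gstk1 in 1 each. The highest edgeR adjusted p was 0.051 for Asb2 (without BALB/c replicate 3), 0.0803 for C1qa and Apoe and 0.129 for Gstk1 (without BALB/c replicate 2), and 0.0961 for Coro1a and 0.0974 for Adamdec1 and Tspan9 (without dblGATA1 replicate 4).

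Of the gene lists tested in the epithelial fraction 12 passed camera, 0 with an estimated correlation and 7 with fry. All 12 measured genes of fatty acid oxidation were lower, none past the threshold over all genes and 9 when adjusted over the list alone, with a median log2 fold change of -0.20 (camera adjusted p = 1.07e-09; adjusted p = 0.0894 with an estimated correlation). Slc25a20, the mitochondrial carnitine carrier, had a log2 fold change of -0.27 (edgeR adjusted p = 0.0633). Of 15 cholesterol synthesis genes 14 were higher, 7 of them passing when adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 1.18e-06; adjusted p = 0.206 with an estimated correlation). Macrophage genes were higher in 8 of 9 members, 5 when adjusted over the list alone (median 1.16, camera adjusted p = 7.35e-07; adjusted p = 0.136 with an estimated correlation), with Csf1r, the receptor for CSF1, at a log2 fold change of 1.71 (edgeR adjusted p = 0.0633). All 8 extracellular matrix genes (6 when adjusted over the list alone; camera adjusted p = 2.59e-05; adjusted p = 0.161 with an estimated correlation), all 6 T cell genes (5; 0.000131; adjusted p = 0.283) and all 8 cytotoxic lymphocyte genes (4; 4.37e-06; adjusted p = 0.237) were higher. The 12 enteroendocrine genes were all lower (2 when adjusted over the list alone; camera adjusted p = 0.000131; adjusted p = 0.412 with an estimated correlation), with Gip at a log2 fold change of -0.38. All 12 immediate early and heat shock genes, which respond to tissue handling, were higher, none when adjusted over the list alone (median 0.52, camera adjusted p = 0.00305; adjusted p = 0.425 with an estimated correlation).

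In all, edgeR called 7 of 11997 genes in the epithelial fraction, 6 higher and 1 lower, with 1658 genes at an unadjusted p under 0.05, and DESeq2 called 204. The edgeR count was 3, 1, 0, 14 and 1 without BALB/c replicate 1, 2, 3, 4 or 5, and 4, 1 and 4 without dblGATA1 replicate 3, 4 or 5. The count of 0 came with 1563 genes at an unadjusted p under 0.05.

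In the lamina propria, several genes of eosinophils and other granulocytes were lower in dblGATA1 mice. Alox15, the 15-lipoxygenase of eosinophils, had 7 counts over the 5 dblGATA1 libraries against 860 in BALB/c, a ratio of 138 (95% counting interval 66.6 to 344; edgeR adjusted p = 0.0064). Ccr3, the eotaxin receptor, fell 29.0-fold, from 9.69 ± 11.8 to 0.32 ± 0.163 CPM (edgeR adjusted p = 0.0168; adjusted p 0.0531 without dblGATA1 replicate 1). Nlrp12 (3 against 192 counts, ratio 71.8, interval 24.2 to 351) and Cebpe, a transcription factor of late granulocyte differentiation (3 against 166 counts, ratio 62.1, interval 20.9 to 304), fell as well (edgeR adjusted p = 0.0125 and 0.0165). Retnlg had 0 counts against 305, at least 114-fold lower relative to a floor of 3 counts over the group (edgeR adjusted p = 0.0165; 0.0524 without BALB/c replicate 2). Slco4c1, Serpinb2, Rab44 and Cxcr2, a chemokine receptor of neutrophils, fell by 4.44, 3.98, 3.36 and 2.46 on the log2 scale (edgeR adjusted p from 0.0111 to 0.0345). The call was lost for Cebpe without dblGATA1 replicate 1 (edgeR adjusted p = 0.0508), and Cxcr2 passed in 4 of 10 fits that left out 1 library (highest 0.0838, without BALB/c replicate 2). BALB/c replicate 1 carries much of these sizes: without it the ratio was 78.2 for Alox15 (interval 37.6 to 196) and 29.1 for Cebpe (9.51 to 145), the bound for Retnlg 61.1-fold, the Ccr3 fall 13.3-fold, and the log2 fold changes of Slco4c1 and Serpinb2 were -3.79 and -3.35. Without dblGATA1 replicate 4 the Nlrp12 ratio was 171 (interval 30.3 to 6780), and without dblGATA1 replicate 5 Cxcr2 fell by 3.09 on the log2 scale. Of 4 measured genes of the neutrophil list 2 fell and 2 were higher, 1 of them passing when adjusted over the list alone, and the list did not pass camera (median log2 fold change -1.11, camera adjusted p = 0.28; adjusted p = 0.779 with an estimated correlation).

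Not all eosinophil markers followed. Of 6 measured genes of the eosinophil list, Alox15 and Ccr3 fell, while Ear2 was 3.10 ± 0.729 CPM in dblGATA1 against 1.17 ± 0.939 CPM in BALB/c (edgeR adjusted p = 0.0548; passing when adjusted over the list alone), and Prg2, Siglec5 and Il5ra had log2 fold changes of 0.55, -0.44 and -0.33 (edgeR adjusted p from 0.561 to 0.758). The list did not pass camera (median log2 fold change -0.38, camera adjusted p = 0.585; adjusted p = 0.914 with an estimated correlation). Epx, the eosinophil peroxidase, stayed below the filter on low counts and was not tested. It had 8 counts in dblGATA1 (at most 0.192 CPM in a library) against 31 in BALB/c (at least 0.217 CPM), here on total counts without TMM scaling. Eosinophil levels also varied among BALB/c libraries: replicate 1 was highest for Alox15, at 41.2 CPM against 4.70 to 13.9 CPM in the other 4.

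**Figure D1:**
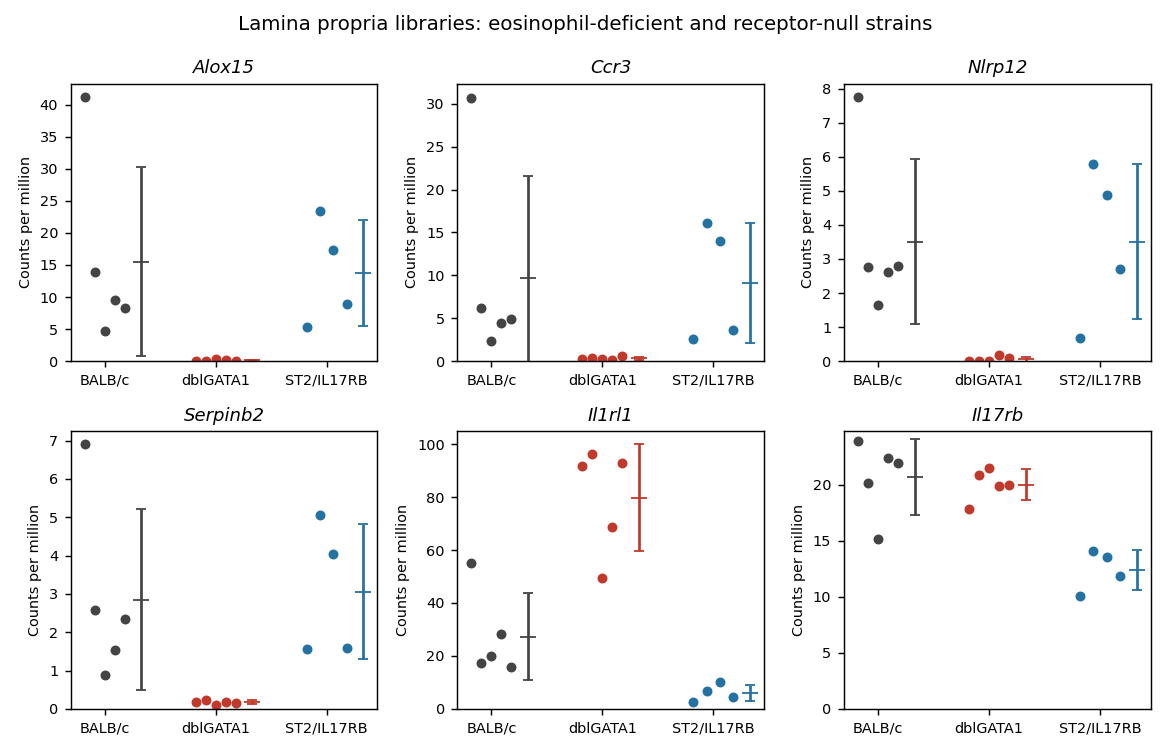
CPM of Alox15, Ccr3, Nlrp12, Serpinb2, Il1rl1 and Il17rb in each lamina propria library (y axis, from 0; points, libraries; side marks, mean and SD) of BALB/c (n = 5), dblGATA1 (n = 5) and ST2/IL17RB null mice (n = 4). The first 4 genes lie near 0 in dblGATA1, with Alox15 at 0.126 ± 0.113 CPM, and the receptor genes are lowest in ST2/IL17RB null.

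Genes of chemokines, macrophages, proteases and interferon responses were higher in the dblGATA1 lamina propria. Ccl24 (eotaxin-2) rose 3.67-fold to 64.8 ± 20.4 CPM and Ccl11 (eotaxin-1) 2.74-fold to 89.1 ± 28.2 CPM, and Il1rl1 rose 2.92-fold to 79.8 ± 20.1 CPM (edgeR adjusted p = 0.0319, 0.0442 and 0.0302). All 7 genes of the alarmin and eosinophil chemokine list were higher, 2 past the threshold and 7 when adjusted over the list alone (camera adjusted p = 0.000352; adjusted p = 0.558 with an estimated correlation). Of 13 macrophage genes 6 rose and 9 passed when adjusted over the list alone (camera adjusted p = 1.86e-05; adjusted p = 0.558 with an estimated correlation), with Csf1r at 925 ± 247 against 366 ± 176 CPM. C3ar1, the receptor for complement C3a, rose 3.39-fold, and Cd209b and Cd209c, C-type lectins of a family of close copies whose reads may be shared, rose 3.79-fold and 3.68-fold. Of 13 matrix remodelling genes 4 rose and 6 passed when adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.645 with an estimated correlation), the metalloproteases Mmp2, Mmp9, Mmp10 and Mmp13, by 1.91-fold to 3.65-fold (Mmp10 6.02-fold without BALB/c replicate 1). All 15 type I interferon response genes were higher, 6 past the threshold, Ifi44 and Oas3 among them, and 14 when adjusted over the list alone (camera adjusted p = 3.38e-07; adjusted p = 0.558 with an estimated correlation). All 17 interferon gamma response genes were higher, none past the threshold and 9 when adjusted over the list alone (camera adjusted p = 2.95e-05; adjusted p = 0.558 with an estimated correlation), and of 10 cytotoxic lymphocyte genes 3 rose, Klrk1 and Gzmb among them, and 9 passed over the list alone (1.86e-05; adjusted p = 0.558).

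Genes of red cells, nerve and muscle also differed in the dblGATA1 lamina propria. Of 8 erythroid and platelet genes 3 rose, 1 fell and 7 rose when adjusted over the list alone (camera adjusted p = 0.00532; adjusted p = 0.558 with an estimated correlation). Hbb-bs and Hba-a1, haemoglobin chains with close copies that can share reads, rose 3.24-fold and 3.40-fold. All 14 enteric neuron genes were lower, 7 past the threshold and 13 when adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 3.25e-07; adjusted p = 0.558 with an estimated correlation). Ret, the receptor for glial-derived neurotrophic factor, fell 1.76-fold, from 49.8 ± 8.16 to 28.3 ± 3.51 CPM, and Nos1, the neuronal nitric oxide synthase, 2.52-fold (edgeR adjusted p = 0.0137 and 0.0241). All 6 glial genes were lower, 3 past the threshold (camera adjusted p = 0.000352; adjusted p = 0.558 with an estimated correlation), such as S100b at 4.55 ± 1.10 against 8.79 ± 1.93 CPM. Of 15 smooth muscle genes 14 were lower, 2 past the threshold and 8 when adjusted over the list alone (median -0.58, camera adjusted p = 0.000433; adjusted p = 0.645 with an estimated correlation), the contractile and filament genes Smtn and Synm at log2 fold changes of -0.97 and -1.24. Eln, elastin, fell 2.46-fold (edgeR adjusted p = 0.0064). Nos1, S100b, Smtn and Synm passed in 6, 6, 6 and 3 of 10 fits that each left out 1 library (highest edgeR adjusted p 0.0752, 0.0674, 0.0763 and 0.103, without BALB/c replicate 2).

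Over all genes, edgeR called 1361 of 15397 in this comparison, 628 higher and 733 lower, and 432 of these changed more than 2-fold. The count was 34, 41 and 54 without BALB/c replicate 2, BALB/c replicate 5 or dblGATA1 replicate 1, 269, 376, 459 and 299 without BALB/c replicate 3 or dblGATA1 replicates 2, 3 or 5, and 2060 and 2160 without BALB/c replicates 1 or 4. Without the 5 libraries of outlying B cell or enterocyte content it was 144 (25 higher), and with GC trends removed 495. Without BALB/c replicate 2, every rise named above missed the threshold (adjusted p from 0.0585 for Cd209c to 0.121 for Mmp10), as without BALB/c replicate 5. Alox15, Nlrp12, Serpinb2, Rab44, Ret and Eln passed in every fit that left out 1 library and under every other alternative that tested them.

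In the lamina propria of ST2/IL17RB null mice, genes of the enteric nervous system were lower than in BALB/c. Ret fell 2.29-fold, from 49.8 ± 8.16 (n = 5) to 21.7 ± 2.16 CPM (n = 4; edgeR adjusted p = 0.00162). Vip, a neuropeptide, fell 2.35-fold, and Calcb, the beta form of calcitonin gene-related peptide, 5.27-fold (edgeR adjusted p = 0.00964 and 0.0064). Of 14 enteric neuron genes 13 fell, and 13 passed when adjusted over the list alone (median log2 fold change -1.53, camera adjusted p = 1.76e-11; adjusted p = 0.897 with an estimated correlation). Of 6 glial genes 5 fell, among them S100b, Gfap and Sox10 by 1.28 to 1.40 on the log2 scale (camera adjusted p = 5.8e-07; adjusted p = 0.386 with an estimated correlation). Lists that describe sample makeup and RNA quality moved in the same comparison: all 10 epithelial carry-over genes were higher (median log2 fold change 0.56, camera adjusted p = 0.0136; adjusted p = 0.967 with an estimated correlation) and all 7 mitochondrial messengers lower (camera adjusted p = 0.0123; adjusted p = 0.967).

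Muscle and matrix genes were lower too. All 15 smooth muscle genes were lower, 4 past the threshold and 13 when adjusted over the list alone (median log2 fold change -0.89, camera adjusted p = 5.8e-07; adjusted p = 0.967 with an estimated correlation). Smtn stood at 166 ± 29.3 against 347 ± 100 CPM, and Acta2, smooth muscle actin, had a log2 fold change of -1.02 (edgeR adjusted p = 0.0146 and 0.0496). Of 9 fits that each left out 1 library, Smtn passed in 4 and Acta2 in 1 (highest adjusted p 0.0598 and 0.153, without BALB/c replicate 5), and Acta2 passed in 3 of 10 other alternatives. Of 17 extracellular matrix genes 3 fell and 4 passed when adjusted over the list alone (camera adjusted p = 0.0054; adjusted p = 0.967 with an estimated correlation), Eln, Postn and Lum, by 1.49-fold to 2.05-fold. These passed in 8, 7 and 1 of the 9 fits (highest edgeR adjusted p 0.051 and 0.0657 without ST2/IL17RB null replicate 2, and 0.122 without BALB/c replicate 5). Among called genes of at least 1 CPM with no overlap between groups, the largest falls were those of Car3, a muscle and fat carbonic anhydrase (7 counts against 462, ratio 61.9, 95% counting interval 29.8 to 155; without BALB/c replicate 2 28.4, interval 13.5 to 71.8), and Myl1, a myosin light chain (17 against 185 counts, ratio 10.2, interval 6.2 to 17.9), with edgeR adjusted p = 0.013 and 0.00338. Car3 missed the threshold without ST2/IL17RB null replicate 2 (edgeR adjusted p = 0.055).

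Fewer genes were higher in ST2/IL17RB null mice. Hspe1, a mitochondrial chaperone with many processed copies that can share reads, rose 4.12-fold, Mt2, a metallothionein, 4.11-fold, and Cux2, a homeobox transcription factor, 3.60-fold (edgeR adjusted p = 9.39e-05, 0.00344 and 0.00189). H2-Q7, a class I histocompatibility gene with near-identical neighbours, had a log2 fold change of 2.46 (edgeR adjusted p = 0.00461). The mucosal mast cell proteases Mcpt1 and Mcpt2 rose 3.22-fold and 3.04-fold (edgeR adjusted p = 0.0425 and 0.0298), though each missed the threshold when ST2/IL17RB null replicate 4 or 2, among others, was left out (adjusted p = 0.11 and 0.0889). Of the 9 measured mast cell genes 5 were higher and 4 lower, 2 rose and 1 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.436; adjusted p = 0.967 with an estimated correlation). Eosinophil genes did not differ detectably: Alox15 stood at 13.8 ± 8.22 against 15.5 ± 14.7 CPM and Ccr3 at 9.08 ± 6.98 against 9.69 ± 11.8 CPM (edgeR adjusted p = 0.899 and 0.956), and none of the 6 listed genes passed (camera adjusted p = 0.706; adjusted p = 0.984 with an estimated correlation). The test points up while the median log2 fold change is -0.03.

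Over all genes, edgeR called 1186 of 15397, 186 higher and 1000 lower, and 528 of the 543 genes that changed more than 2-fold were lower. The count was 419, 553 and 324 without BALB/c replicates 2, 3 or 5, 351, 649 and 501 without ST2/IL17RB null replicates 2, 3 or 4, and 1994 without BALB/c replicate 4. It was 401 when only these 2 groups were fitted, and 1807 without the 5 libraries of outlying content.

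Set against each other, the mutants differed past the threshold over all genes in 1 of the 3 targeted genes. When adjusted over these genes alone, 1 was higher and 2 were lower in ST2/IL17RB null. Il1rl1 was 13.3-fold lower in ST2/IL17RB null than in dblGATA1 (5.97 ± 3.15 against 79.8 ± 20.1 CPM; edgeR adjusted p = 0.00282). Alox15 was higher in ST2/IL17RB null (700 counts against 7, ratio 120, interval 57.8 to 299), as were Nlrp12 (179 against 3, ratio 71.4, interval 24 to 350; without dblGATA1 replicate 4 170, interval 30.1 to 6750), Slco4c1, Serpinb2 and Rab44 (edgeR adjusted p from 0.00399 to 0.0416). Gata1, Ccr3 and Retnlg had edgeR adjusted p of 0.0839, 0.065 and 0.0612, and Il17rb 0.0664. Cux2, Mt2 and Hspe1 were 5.69-fold, 5.11-fold and 3.96-fold higher in ST2/IL17RB null (edgeR adjusted p = 0.000211, 0.00282 and 0.000112). Adhfe1, an alcohol dehydrogenase family gene, was 4.90-fold lower and Tlr2, a receptor for bacterial lipoproteins, 1.77-fold lower (edgeR adjusted p = 0.00454 and 0.0475). Of 9 fits that each left out 1 library, Nlrp12 passed in 5, Slco4c1 in 4, Serpinb2 in 3, Rab44 in 2 and Tlr2 in 1. The highest edgeR adjusted p was 0.076 for Nlrp12 (without dblGATA1 replicate 2), 0.0952 for Slco4c1 and 0.0964 for Serpinb2 (without dblGATA1 replicate 5), 0.136 for Rab44 (without dblGATA1 replicate 1) and 0.191 for Tlr2 (without ST2/IL17RB null replicate 4), and Tlr2 passed in 6 of 10 other alternatives.

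This comparison gave 22 called genes of 15397, 11 in each direction, with 3197 at an unadjusted p under 0.05, while DESeq2 called 651. The count was 1238 without dblGATA1 replicate 4, 11, 10 and 10 without dblGATA1 replicates 1, 2 or 5, 14, 10 and 13 without ST2/IL17RB null replicates 1, 2 or 4, and 903 without the 5 libraries of outlying content. Neither the neuron nor the glia list had a member past the threshold between the mutants (camera adjusted p = 0.00479 and 0.0184, lower in ST2/IL17RB null; adjusted p = 0.601 and 0.556 with an estimated correlation).

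The dblGATA1 effect differed between the fractions for some genes. The interaction test called 812 of 15698 genes, 476 with a higher log2 fold change in the lamina propria and 336 with a lower one, and 482 of them were among the 1357 genes called in the lamina propria and tested here. DESeq2 called 1468, while edgeR with the replicate number as a replicate block called 0, with 2868 genes at an unadjusted p under 0.05. Of the 7 genes called in the epithelial fraction, Tspan9 passed it, with log2 fold changes of 1.01 in the epithelial fraction and -0.01 in the lamina propria (edgeR adjusted p = 0.0348). Apoe and Adamdec1 were called higher in both fractions, with lamina propria log2 fold changes of 1.23 and 1.22 (edgeR adjusted p = 0.0242 and 0.0356). The count was 518, 435, 463 and 430 without epithelial BALB/c replicates 2, 3, 4 or 5, 425 and 431 without epithelial dblGATA1 replicates 4 or 5, 1422, 377 and 451 without lamina propria BALB/c replicates 1, 2 or 5, and 421 and 489 without lamina propria dblGATA1 replicates 1 or 5. The kit and the counting differ between fractions, so the test holds only if neither acts on fold changes.

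Changes in the lamina propria overlapped between the mutant strains. Of the genes called in both, 48 were higher and 439 lower in both, Ret, Eln, Smtn and S100b among the latter, and 2 went opposite ways. Both comparisons use the same BALB/c libraries. Independent lists of these sizes would share 7.59 and 47.6 genes. Log2 fold changes correlated across genes with r = 0.588 (rho = 0.509), against a median r of 0.472 (0.451 to 0.494) in 20 runs of simulated unchanged groups against these controls, and their covariance was 0.122 against 0.0382 (0.0366 to 0.042). The simulation drew each gene independently, so it lacks the differences in B cell and enterocyte content that move many genes together in these libraries. The excess over the simulated r and covariance therefore cannot be read as a common effect of the mutations. The simulated groups called at most 1 and 2 genes, so they give no count of shared genes to compare. With the controls split into 2 and 3 libraries (20 splits), the median r was 0.254 (-0.0637 to 0.468), the median rho 0.222 and the median covariance 0.072 (-0.0228 to 0.112). The lists in these splits held a median of 28.5 and 154 genes, so the 4 genes they shared at the median cannot be set against 487. The overlap of 487 genes was 19, 20 and 114 without BALB/c replicates 2, 5 or 3 and 1024 without BALB/c replicate 4, 33, 224, 194 and 159 without dblGATA1 replicates 1, 2, 3 or 5, 165 and 317 without ST2/IL17RB null replicates 2 or 4, and 116 without the 5 libraries of outlying content. Between fractions the dblGATA1 calls shared 2 genes, Apoe and Adamdec1, where independent lists would share 0.247 higher genes, and log2 fold changes across 11816 genes had r = 0.063 and rho = -0.125. This overlap fell to 0 without epithelial BALB/c replicate 1, 2, 3 or 5, epithelial dblGATA1 replicate 4, lamina propria BALB/c replicate 2, 3 or 5 or lamina propria dblGATA1 replicate 1 or 2, and to 1 without epithelial dblGATA1 replicate 1, 2 or 3 or lamina propria dblGATA1 replicate 3 or 5. DESeq2 calls shared 29 genes.

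Genes near the targeted loci were tested because a deletion made in another strain can carry neighbouring DNA with it. Within 10 Mb of Gata1, called genes were not enriched for dblGATA1 in the lamina propria or the epithelial fraction (Fisher's exact p = 0.354 and 1), nor within 10 Mb of Il1rl1 or Il17rb for ST2/IL17RB null against BALB/c (p = 1 and 0.862). For ST2/IL17RB null against dblGATA1 they were enriched around Il1rl1 (Fisher's exact p = 0.00658), but with Il1rl1 itself left out the exact p was 0.109. Without the 5 libraries of outlying content, and with Il1rl1 counted, the exact p was 0.819 (odds ratio 0.784), so no enrichment was detectable. Within 20 Mb the exact p was 9.92e-05, and 0.00161 with Il1rl1 left out (3 of 172 genes against 18 of 15097), but 0.0725 and 0.14 without the 5 libraries. Within 10 Mb, leaving out dblGATA1 replicate 1, 2, 4 or 5 gave an exact p of 0.0597, 0.0538, 0.554 and 0.0545, and leaving out ST2/IL17RB null replicate 1, 2, 3 or 4 gave 0.0755, 0.0546, 0.091 and 0.0704.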

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

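The tests of GC content and of muscle layer were chosen only after the results were seen. So were those of a single share of whole lamina propria and of leukocytes for the matrix genes. The other tests of this part were written down before. Of these, the tests of carry-over and of a single library were written for patterns already seen. The dblGATA1 library left out there, replicate 1, was picked because it stood apart from the others. In 267 tests of whether 1 sample of a group lay far from the rest (chance marks about 1 in 20), 23 did, and 18 of these are BALB/c lamina propria replicate 1 lying highest. There, the eosinophil list genes Alox15 (41.2 CPM), Ccr3 (30.7), Ear2 (2.85), Prg2 (3.71) and Siglec5 (12.3), and Retnlg (15.3), Nlrp12 (7.76), Cebpe (9.05), Slco4c1 (9.74) and Serpinb2 (6.9), which fell in dblGATA1, stood above the other 4 BALB/c libraries, in which Alox15 ran from 4.70 to 13.9 CPM and Ccr3 from 2.29 to 6.14 CPM. So did the chemokine, macrophage, protease and cytotoxic lymphocyte genes Ccl24 (38.7 CPM), Cd209b (26.1), Mmp9 (40), Mmp10 (181), Mmp13 (36.6), Csf1r (678), Cx3cr1 (126) and Klrk1 (15.5). Stmn2 was lowest in BALB/c lamina propria replicate 4 (15.7 CPM against 28.4 to 33.4), and Ret in ST2/IL17RB null replicate 3 (18.5 against 22.4 to 23.1). In the epithelial fraction, dblGATA1 replicate 4 had the lowest total (24500679 counts against 28707431 to 29582764), Col3a1 was highest in dblGATA1 replicate 1 (3.00 CPM against 1.60 to 1.80) and Cgn, a tight junction gene, lowest in BALB/c replicate 1 (146 CPM against 159 to 162).

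The dblGATA1 effect differed between fractions for 6 named genes by the edgeR interaction test, which called 812 genes, but 0 with the replicate number as a replicate block (2868 at an unadjusted p under 0.05; DESeq2 without the block 1468). The lamina propria minus epithelial difference of log2 fold changes was -4.36 for Rab44 (adjusted p = 0.00663), -0.94 for Avil, a tuft cell gene (0.0116), -1.21 for Smtn (0.0226), 1.35 for Oas3 (0.0337), -1.02 for Tspan9 (0.0348) and -1.20 for Col3a1 (0.0418).

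Of 100 drawn splits of the libraries into groups of the same sizes, the real one included, few called as many genes as the real split. In the epithelial fraction 2 of 100 did (real 7, highest other 147). In the lamina propria 3 of 100 did for dblGATA1 against BALB/c (1361, highest other 2775), 2 for ST2/IL17RB null against BALB/c (1186, highest other 1909), 3 between the mutants (22, highest other 3520), and 2 for the interaction (812, highest other 1650). These shares are each under 0.05, without adjustment over the comparisons, so they argue against chance for the counts of genes but do not exclude it. Splits that call several times the real count, as in the epithelial fraction and between the mutants, point to a structure of the samples beyond the groups. For gene lists chance cannot be excluded: 13 of 100 splits had as many lists past camera in the epithelial fraction (real 12, highest other 17), and in the lamina propria 26 for dblGATA1 (19, highest other 28), 93 for ST2/IL17RB null (9, highest other 26) and 24 between the mutants (21, highest other 27).

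Enteric neuron and glial genes lay below BALB/c in both mutant strains, most in ST2/IL17RB null (median log2 fold change of 20 genes -1.45, 18 called lower), which as a hypothesis may reflect a smaller share of nerve tissue. GC content is argued against as the whole account: with GC trends removed the ST2/IL17RB null median was -1.40 (quartiles -1.55 and -1.24) with 18 genes called lower, and the dblGATA1 median went from -0.81 to -0.94 with 8 in place of 10 called lower. For ST2/IL17RB null a single library is argued against as well: leaving out each library in turn left at least 11 of the 20 genes called lower, the lowest count without BALB/c replicate 5 or ST2/IL17RB null replicate 2, with 12 without BALB/c replicate 2. Less muscle layer, which holds most enteric neurons, predicts that smooth muscle genes fall as far, but their median lay 0.561 above that of neuron and glial genes (0.46 to 0.615 without any 1 library, a range of 0.155). That met the bound written against this explanation. Less muscle layer is still left open, a choice made after the result was seen. The reason is that smooth muscle genes themselves fell (median -0.89) and muscle of the mucosa stays in this fraction. The genotype is open as well, and the 2 cannot be told apart here. The ST2/IL17RB null libraries also had all 10 epithelial carry-over genes higher, and all 7 mitochondrial messengers were lower in both mutant strains.

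Macrophage, T cell and matrix genes were higher in the epithelial fraction of dblGATA1 mice, and more lamina propria left on the epithelium is a candidate explanation. Genes at least 10 times higher in BALB/c lamina propria than in BALB/c epithelial libraries numbered 1343. Of these, a share of 0.757 (1016 genes) was higher in dblGATA1, against 0.506 of all tested genes. The choice favours a low BALB/c epithelial level, the base of the fold change, which by itself can raise the share. The share of 0.506 carries no such choice and is no control for it. The 0.757 lies between the bounds written down for and against carry-over and so leaves it open. One share of whole lamina propria added to every class is argued against: the rise as a percentage of the lamina propria level had a median of 0.59 for macrophage genes (quartiles 0.413 and 0.726) and 0.0389 for matrix genes (0.0275 and 0.0701), a ratio of 15.2, and of 9.34 for T cell genes (4.02 and 15.4), although the kits differ between the fractions. For the lamina propria-rich genes as a set, dblGATA1 replicate 1 as the sole source is argued against. Their median log2 fold change was 0.18 and 0.148 without replicate 1, a ratio of 0.82. The macrophage, T cell and matrix lists were not tested without that library, so this does not settle a single library for them. For the leukocyte genes, a change in leukocytes and carry-over of another composition cannot be told apart. For the matrix genes, which are not on the leukocyte lists, a change in leukocytes alone would predict no rise. All 8 measured matrix genes, of 17 listed, were higher (median log2 fold change 1.01, lower quartile 0.69). Relative to the mean of the fraction, their log2 level was at least 0.116 in dblGATA1 libraries and at most -0.181 in BALB/c libraries. Smooth muscle and endothelium genes hardly moved (medians 0.13 and 0.06). The matrix rise is part of the pattern itself, so it is no independent test and cannot decide on leukocytes alone.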

How the results depend on the processing

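The GC correction, the fits without libraries of outlying B cell or enterocyte content, the covariates and the locus test without its target were chosen after seeing the data. Of the counts of changed genes, that of the epithelial fraction (7) was 11 with no low-count filter, 204 with DESeq2 and 0 to 14 without any 1 library (0, with 1563 genes at an unadjusted p under 0.05, without BALB/c replicate 3). In the lamina propria, dblGATA1 against BALB/c (1361) gave 2480 with DESeq2, 495 with the GC correction, 144 without 5 libraries, 3698 with covariates and 34 to 2160 without any 1 library. ST2/IL17RB null against BALB/c (1186) gave 1850, 401 with 2 groups fitted, 1807 without 5 libraries, 1809 with covariates and 324 to 1994 without any 1. Between the mutants (22) it was 651, 903, 159 and 10 to 1238, in the order DESeq2, 5 libraries, covariates and 1 library left out. The interaction (812) gave 1468 with DESeq2, 1674 without 4 libraries and 377 to 1422 without any 1. Lists past camera (12, 19, 9 and 21) numbered 0 in each comparison with an estimated correlation and 7, 2, 2 and 1 with fry. The overlap of the mutant strains (487) was 951 at adjusted p under 0.1, 901 with DESeq2, 116 without 5 libraries and 19 to 1024 without any 1, and that of the fractions (2) was 11, 29 and 0 to 3. The exact p near Il1rl1 between the mutants (0.00658) was 0.0923 within 5 Mb, 9.92e-05 within 20 Mb and 0.109 without Il1rl1. It was 0.819 without 5 libraries and 0.00703 to 0.554 without any 1 library. At 0.819 and 0.554 the odds ratio lay below 1, which is no detectable reversal. Fewer samples were fitted where libraries were left out; for the rest the cause was not tested. Correlations of deviations between same-numbered lamina propria libraries of different genotypes ran from -0.533 to 0.606. Between the fractions of a genotype they ran from -0.0865 to 0.163. The latter compare unlike tissues and cannot settle whether same-numbered libraries share a mouse. With the replicate number as a replicate block, the counts were 7, 210, 530 and 8. For the interaction the block takes same-numbered libraries of a genotype as 1 mouse. The count was then 0 (edgeR, 2868 genes at an unadjusted p under 0.05, smallest adjusted p 0.0502). The overlaps with the block held 125 and 0 genes. The other alternatives that used all libraries kept every count within 1.5 times. Of the named calls, 4 of 7 in the epithelial fraction, 8 of 43 and 20 of 40 against BALB/c in the lamina propria and 3 of 16 between the mutants passed under every alternative fit, 0, 8, 20 and 6 without any 1 library, and 0 reversed. Depth limits low genes: at 3 counts over a group the lamina propria floor is 0.051 to 0.061 CPM.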

Other observations

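Both tests of chromosome 1 genes, and the test of donor DNA within 20 Mb, were chosen only after the results were seen. The test of tissue makeup near Il1rl1 was written down before, though after the list levels that set the 5 libraries were seen. Genes of dividing cells and of hormone-producing epithelium were higher in the ST2/IL17RB null lamina propria. All 16 proliferation genes were above BALB/c, Pcna past the threshold (55.0 ± 4.57 against 38.5 ± 8.88 CPM, edgeR adjusted p = 0.0451) and 8 when adjusted over the list alone (camera adjusted p = 5.8e-07; adjusted p = 0.967 with an estimated correlation), and against dblGATA1 10 rose when adjusted over the list alone (camera adjusted p = 1.67e-08; adjusted p = 0.556 with an estimated correlation). Of 11 enteroendocrine genes Cck, a gut peptide hormone, and Chgb, a granule protein, rose against BALB/c by log2 fold changes of 1.32 and 1.06 (edgeR adjusted p = 0.0463 and 0.0407; camera adjusted p = 0.000115; adjusted p = 0.967 with an estimated correlation). These single-gene calls rest on few libraries: of 9 fits that each left out 1 library of the compared groups, Cck and Chgb each passed in 1 and Pcna in 2, with the highest adjusted p without ST2/IL17RB null replicate 4 (edgeR; 0.154, 0.134 and 0.0882). The 10 genes listed as a sign of epithelial carry-over were all higher as well, none when adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.967 with an estimated correlation). Cd8b1, a CD8 chain, rose by 1.29 on the log2 scale (edgeR adjusted p = 0.0202) and passed in 7 of 9 such fits (highest adjusted p 0.0574, without BALB/c replicate 5).

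Chemokine and protease genes that were high in dblGATA1 were lower in ST2/IL17RB null than in dblGATA1, but their lists did not pass camera against BALB/c. The same dblGATA1 libraries serve in the comparison that showed these genes high, so the fall is no independent result. All 7 alarmin and eosinophil chemokine genes lay below dblGATA1, none past the threshold over all genes and 6 when adjusted over the list alone (median log2 fold change -1.46, camera adjusted p = 4.01e-05; adjusted p = 0.556 with an estimated correlation); Ccl11 stood at 32.4 ± 13.5 against 89.1 ± 28.2 CPM. All 13 matrix remodelling genes were lower, 7 when adjusted over the list alone (camera adjusted p = 3.48e-05, adjusted p = 0.556 with an estimated correlation), with Mmp9 at 25.3 ± 11.2 against 79.9 ± 24.2 CPM. Against BALB/c the 2 lists had median log2 fold changes of -0.08 and -0.14 (camera adjusted p = 0.571 and 0.462). Between the mutants, 9 of 10 epithelial carry-over genes were also higher and all 12 immediate early and heat shock genes lower in ST2/IL17RB null (camera adjusted p = 0.00102 and 0.00479, adjusted p = 0.556 for each with an estimated correlation). In the epithelial fraction, all 8 Paneth cell genes and 8 of 9 goblet cell genes were lower in dblGATA1 and 15 of 16 proliferation genes higher, with none past the threshold (camera adjusted p = 0.0161, 0.0406 and 0.0398; adjusted p = 0.57, 0.57 and 0.771 with an estimated correlation). In the lamina propria, mt-Nd6, a mitochondrially encoded gene, fell by 1.06 on the log2 scale in dblGATA1 and by 0.65 in ST2/IL17RB null (edgeR adjusted p = 0.0137 and 0.0342). Counting in this fraction ignored the strand, so reads antisense to mt-Nd6 cannot be told apart from its own. All 7 measured mitochondrial messengers were lower in both strains (camera adjusted p = 0.0333 and 0.0123; adjusted p = 0.742 and 0.967 with an estimated correlation). With 1 library left out, the fall of mt-Nd6 passed in all 10 fits for dblGATA1 but in 3 of 9 for ST2/IL17RB null (highest adjusted p 0.113, without BALB/c replicate 5).

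Of the 22 genes that differed between the mutants, 9 lie on chromosome 1, which holds 6.15% of tested genes (Fisher's exact p = 2.91e-06), and of the 16 that also differed from BALB/c 7 do (p = 2.28e-05 by the same exact test): Adhfe1, Il1rl1, Dnah7b, Hspe1, Aox1, Myl1 and Hjurp, from position 9547948 to 88277633. A hypothesis is that DNA of another strain came along with the deletion of Il1rl1, and without Il1rl1 the exact p was 0.000164 (6 of 15 genes). Within 20 Mb of Il1rl1 called genes were enriched between the mutants (exact p = 9.92e-05, and 0.00161 without Il1rl1), but not detectably without the 5 libraries of outlying content (exact p = 0.0725 and 0.14), nor against BALB/c (exact p = 0.315), where the p without those 5 (0.192) had no enrichment to remove and decides nothing. Genes called for dblGATA1 against BALB/c, a strain in which Il1rl1 is not targeted, also gathered on chromosome 1 (exact p = 0.0017, odds ratio 1.4), though not detectably within 20 Mb of Il1rl1 (exact p = 0.592), which keeps donor DNA open as an explanation that cannot be told apart from the genotype without sequence reads. Libraries of outlying content are argued against only weakly as the source of the 7 calls, and not of the enrichment. All 7 genes stayed past the threshold in both comparisons without those 5, but that fit called many more genes in both comparisons. Between the mutants, Dnah7b, Aox1 and Myl1 passed in 2, 3 and 2 of 9 fits that left out 1 library. The edgeR adjusted p reached 0.157 for Dnah7b and Aox1 (without ST2/IL17RB null replicate 4) and 0.143 for Myl1 (without dblGATA1 replicate 5).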
